A study of Mus musculus with 48 samples.

How the data were processed

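RNA was measured in 48 libraries of AML12 cells, an immortalised mouse hepatocyte line, by bulk Smart-seq3, a full-length method that starts from little RNA. Per the labels, cells were wild type (WT) or lacked Bmal1 (Bmal1-KO, written KO), and the circadian clock was synchronised with a 1-h pulse of dexamethasone, a glucocorticoid. The number in each title was read as hours, giving 6 times from 18 to 48 h in steps of 6 h. The labels do not say from which moment the hours were counted. Each of the 12 groups of genotype and time held 4 libraries, numbered as in the titles. Nothing in the labels says that the 4 libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

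The deposited table holds whole-number counts for 32377 features, and per the file headers they were taken from accepted, sorted and deduplicated alignments. Per the submitters' processing notes, STAR 2.5.4b and the mm10 (GRCm38) build were used. The counting tool, the gene annotation, the strand setting and the use of molecular identifiers were not given in the sources used here. Per the labels' protocols, several read lengths and instruments were used, and the labels do not tie them to libraries. The table has 180 columns of values. Of these, 48 matched a sample by library name, and the other 132 were not used in any step.

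The files do not pair the features with gene names or identifiers, so a feature is named only by its row in the table, and no name was taken from the place of a row in an annotation. The plan made before the data were examined, with the tests, the alternatives and the rule for features to name, asked for 38 gene lists, the clock genes, the targeted gene Bmal1 and markers of other cell types. None of these could be looked up in unnamed rows, and they were not analysed here. The labels of the KO libraries were therefore not checked against Bmal1 itself. The rule for named genes was used as far as it applies to unnamed rows. For KO against WT it took the largest positive and negative changes among features with an adjusted p under 0.05, an average log2 CPM of at least 4 and the same sign at all 6 times, and for rhythms the largest fitted amplitudes among called features. The rule asked for 10 features in each direction, and since the rows carry no names only the first 2 are given in each direction. For rhythms, the feature with the largest WT amplitude and the only feature called in KO are described.

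Library totals ranged from 72398 to 795991 counts with a median of 387536, an 11-fold range. Counting error alone was therefore larger in the 3 libraries under 100000 counts. Of all features, 18382 had at least 1 count, and 8617 (26.6%) passed the edgeR filterByExpr filter, with a minimum count of 10 and a minimum total of 15. The tested features held 97.3% of the counts. Counts scaled to library size (CPM) were computed from the deposited counts with TMM factors. Replicate libraries were compared pairwise by a chi-square test over features with at least 20 counts in the pair. Over the 72 pairs the statistic per degree of freedom ranged from 1.13 to 6.67, and the largest p was 5.43e-10, so no 2 libraries of the same group agreed within sampling noise, and all 48 were kept.

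KO and WT were compared with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood tests on the counts as deposited. One fit gave each of the 12 groups a mean. KO minus WT was tested as the average over the 6 times and at each time. Rhythms were tested in a second fit with a mean, a cosine and a sine of period 24 h for each genotype. Both wave coefficients were tested together within a genotype and for equality between genotypes. Amplitude is the fitted wave's height above its mean in log2 units. Benjamini-Hochberg adjustment ran over the 8617 features, and an adjusted p under 0.05 is written as a call. Library measures were compared by permutation tests with 100000 resamples over 24 against 24 libraries, and by exact permutation tests with 4 against 4. Features at equal depth are the number expected when 72398 counts are drawn from a library without replacement. All tests were two-sided.

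The fits were tested on simulated counts. These were made from each feature's mean over the 48 libraries, the library depths and the spread within the 12 groups. At each of 2 fold sizes 100 features were changed. No other difference between groups, times or library numbers was simulated, while in the data 45.8% of features were called between KO and WT. The shares recovered and false hold for these simulations and may not carry over to the data. Shares are means over 110 simulations, with the lowest and highest. For KO against WT over all times, 85.4% of 1.5-fold changes (76 to 93%) and 99.2% of 2-fold changes (97 to 100%) were recovered, and 4.73% of the calls were false (1.05 to 7.92%). At 36 h the shares recovered were 9.35% (3 to 19%) and 39.8% (26 to 55%), and at 42 h 22.1% (13 to 32%) and 65.9% (53 to 78%). For a WT rhythm, 22.1% of features with a 1.5-fold peak-to-trough range (12 to 33%) and 66.9% with a 2-fold range (52 to 81%) were recovered. For a rhythm present in WT and absent in KO, the test of the difference recovered 3.53% (0 to 10%) and 27.7% (14 to 43%), so most differences of this size would be missed.

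The alternatives were median-of-ratios size factors, DESeq2 1.42.0, limma 3.58.1 voom with quality weights, other filters, a replicate block, an additive model, a minimum fold of 1.5, fits of fewer samples or times, periods of 22 and 26 h, a linear time term, and each replicate number and each library left out. Leaving out the 3 libraries under 100000 counts, and thinning every library to 72398 counts, fitting the letter of the library name as a block, and fitting the library number as a term in the rhythm and slope fits were added after the data were seen. The library names hold a letter and a number, the only labels that look like a batch. Each of the 4 numbers held 1 genotype and 3 times, so genotypes could not be compared within a number. In each genotype 1 number held 18 to 30 h and another 36 to 48 h, so times before and after this step differ in number as well. Each letter held both genotypes and 1 phase of the 24-h cycle, so KO and WT could be compared within letters, and phases could not.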

Results

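BMAL1 is a core transcription factor of the circadian clock, and the series set out to relate the clock of liver cells to daily rhythms of gene expression. The AML12 data compare WT hepatocytes with Bmal1-KO hepatocytes after a synchronising pulse of dexamethasone. There were 24 libraries of each genotype, with 4 at each of 18, 24, 30, 36, 42 and 48 h. Total counts were 430330 ± 211990 (SD, n = 24) per WT library and 367800 ± 173370 (SD, n = 24) per KO library, and the difference did not exceed the spread between libraries (permutation p = 0.265). The 3 shallowest libraries were WT 24 h replicate 2 with 72398 counts, WT 18 h replicate 2 with 77907 and KO 48 h replicate 3 with 87163. Features are rows of the count table and carry no gene names, so the changes are described by their number, size and timing.

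The libraries separated by genotype, and so by library number, because each number held a single genotype. The first principal component of log2 CPM held 17.5% of the variance, and all 24 WT libraries lay below 0 on it while all 24 KO libraries lay above 0. The 3 shallowest libraries carried 48.2% of the sum of squares on this component. Without them it held 19.9% of the variance, and the 22 WT and 23 KO libraries again lay on opposite sides of 0. Fewer features were detected in KO libraries at equal depth, a gap that cannot be told apart from library number either. In 72398 counts, 9479 ± 90.7 (SD, n = 24) features were expected in WT libraries and 9214 ± 86.1 (SD, n = 24) in KO libraries, a difference of -265. The permutation p was 1e-05, the smallest that the resamples can give. At single times the exact permutation p was 0.0286, the smallest possible with 4 against 4 libraries, at 18, 30, 36, 42 and 48 h (adjusted p = 0.0343), and 0.114 at 24 h. The 100 most abundant features of a library took 20.02% ± 1.04 (SD, n = 24) of the counts in WT and 21.7% ± 1.27 (SD, n = 24) in KO (permutation p = 1e-05, the smallest possible). At 59134 counts, the smallest total left when the same 100 abundant features were removed from every library, the difference was -262 with all features and -209 after the removal.

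**Figure D1:**
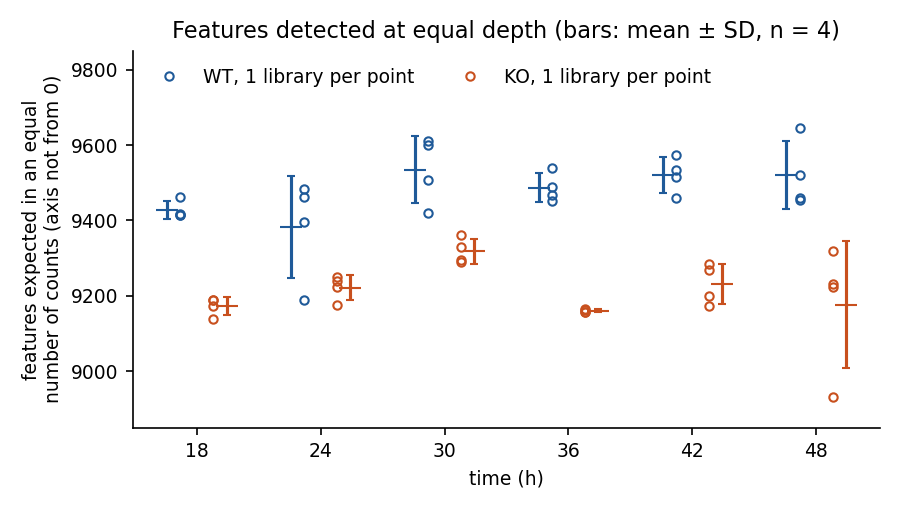
Number of features expected in 72398 counts (vertical axis, not starting at 0) by time in hours, with 1 point per library and the mean ± SD of 4 libraries beside them, WT in blue and KO in orange. KO means lay below WT means at all 6 times, with the largest gap at 48 h (-343.9) and the smallest at 24 h (-160.2). The lowest library of each genotype lay at these times, WT 24 h replicate 2 at 9188 and KO 48 h replicate 3 at 8933. Both had under 100000 counts. The WT library narrowed the 24 h gap and the KO library widened the 48 h gap.

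The loss of Bmal1 was accompanied by many small changes and few large ones. Averaged over the 6 times, 1979 features were higher and 1963 lower in KO, 45.8% of the 8617 tested (edgeR quasi-likelihood, Benjamini-Hochberg). TMM scaling sets the typical change near 0, and the median log2 change of all tested features was -0.007. The balance of rises and falls is therefore relative to this scaling. TMM factors were 1.026 ± 0.022 in WT and 0.975 ± 0.023 in KO libraries (SD, n = 24, permutation p = 1e-05, the smallest possible). With median-of-ratios size factors, 1862 features were higher and 2087 lower. The median size of a called change was 0.43 on the log2 scale, or 1.35-fold, and 2837 calls (72.0%) were under 1.5-fold. At 2-fold or more, 73 features were higher and 149 lower, and 218 of these 222 had the same sign at all 6 times. When tested against a minimum change of 1.5-fold, 159 features were higher and 200 lower. With the letter of the library name as a block, 1971 features were higher and 1944 lower. Every library number held a single genotype, so genotype and library number cannot be told apart.

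The 2 largest increases chosen by the rule were rows 4877 and 4905. Row 4877 was nearly silent in WT cells, with 7 counts over 24 libraries, and had 216 counts over the 24 KO libraries (0.75 ± 1.49 against 26.1 ± 12.7 CPM, SD, n = 24; adjusted p = 1.32e-20, edgeR). No fold is given for it because the WT libraries at 18 and 36 h had no count. Row 4905 rose from 23.2 ± 15.03 to 115.9 ± 58.6 CPM (SD, n = 24), a log2 change of 2.29 (SE 0.13, adjusted p = 6.47e-24, edgeR). Its log2 change was 1.08 (SE 0.29) at 18 h and 1.55 (SE 0.34) at 30 h. It was 2.91 (SE 0.34) at 36 h and 4.05 (SE 0.33) at 48 h. In each genotype the library number changed between 30 and 36 h. The rise across this step therefore cannot be told apart from a difference between library numbers. The 2 largest decreases were rows 29118 and 9555. Row 29118 had 196 counts in WT and 26 in KO libraries, or 16.7 ± 10.7 and 2.80 ± 3.31 CPM (SD, n = 24, adjusted p = 1.32e-10, edgeR), with no count in KO at 36 h. Row 9555 fell from 29.1 ± 15.2 to 4.67 ± 3.34 CPM (SD, n = 24), a log2 change of -2.59 (SE 0.22, adjusted p = 2.48e-16, edgeR). These rows rest on low counts per library, at most 131 in row 4905 and 35 in row 9555.

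At each time the comparison rested on 4 libraries against 4. Relative to the TMM scaling, rises and falls were again about equally frequent. At 18 h, 372 features were higher and 302 lower in KO. The counts were 494 and 421 at 24 h, 417 and 379 at 30 h, and 256 and 220 at 36 h. They were 773 and 628 at 42 h, and 774 and 730 at 48 h (edgeR quasi-likelihood, Benjamini-Hochberg). Of 2679 features called at 1 or more times, 135 were called at all 6, with 75 higher and 60 lower. Among 1367 features called at 2 or more times, 8 had calls of both signs. Across the 3961 features with an average log2 CPM of at least 6, the log2 changes at 2 different times correlated at 0.615 to 0.855 over the 15 pairs of times, a relation across features, which are not independent replicates. Libraries at 36 h were the shallowest, at 259432 counts on average, and those at 42 h the deepest, at 519653. Single libraries decided part of these counts. The 476 calls at 36 h were 243 without WT 36 h replicate 2, 316 without KO 36 h replicate 3 and 293 without KO 36 h replicate 4. The 796 calls at 30 h were 472 without WT 30 h replicate 4, and the 1504 at 48 h were 998 without KO 48 h replicate 1.

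**Figure D2:**
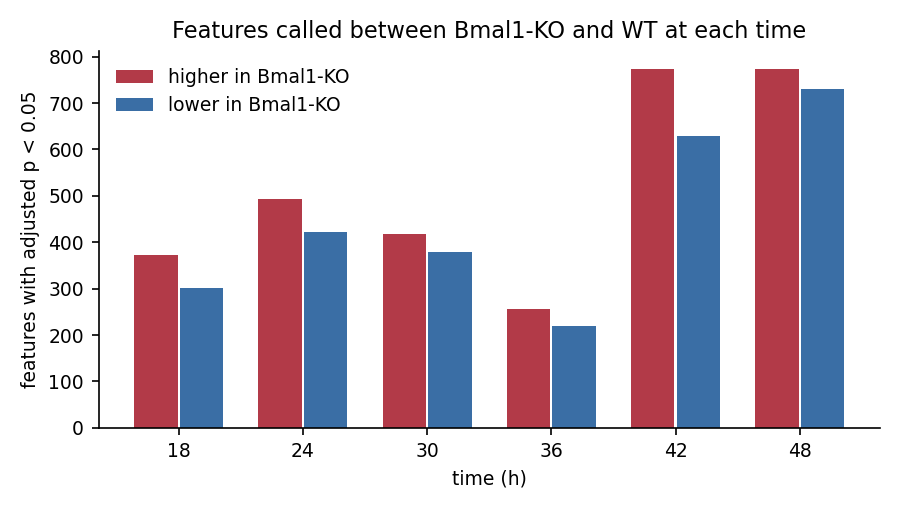
Number of features with an adjusted p under 0.05 (vertical axis) by time in hours, with red bars for features higher and blue bars for features lower in KO. Calls ranged from 256 higher and 220 lower at 36 h to 774 higher and 730 lower at 48 h.

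Rhythms were sought because a synchronised clock should give waves of about 24 h. With the cosine model, 33 features had a 24-h rhythm in WT and 1 in KO, and the KO feature was also among the 33 (edgeR quasi-likelihood, Benjamini-Hochberg). Of 100 assignments of times within genotypes, the real one included, 6 gave as many WT calls. The highest other gave 101, so chance is not excluded for the number in WT. No feature passed the test of a different rhythm between genotypes, with 317 at an unadjusted p under 0.05 where 430.8 were expected by chance, and DESeq2 and limma also called 0. The larger number in WT is therefore not shown to be a difference between genotypes. When each genotype was fitted alone, 16 features were called in WT and 18 in KO. With the library number as a term, 126 were called in WT, 3 in KO and 0 for the difference. The 33 features had a median peak-to-trough range of 2.00-fold in WT, and their median amplitude was 0.50 in WT against 0.26 in KO. Amplitude was larger in WT for 31 of the 33, a comparison that favours WT because the features were selected there. Adjusted over these 33 alone, 3 differed between genotypes, all with the smaller amplitude in KO. Leaving out WT 24 h replicate 2 raised the WT calls to 70. The KO calls were 2 when any of WT 48 h replicate 2, KO 18 h replicate 4, KO 24 h replicates 1 and 4 or KO 30 h replicate 1 was left out.

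The feature with the largest WT amplitude had a mean of 1352 CPM in WT. It was at 434.5 ± 31.7 CPM at 36 h and at 2191 ± 312 CPM at 30 h (SD, n = 4), with a fitted range of 3.63-fold and a fitted peak at 26.1 h (adjusted p = 1.85e-08, edgeR). These 2 times had its lowest and highest WT means, and the library number changed between them. In KO it was lower at every time, at 325.6 ± 129.1 CPM over 24 libraries, a log2 change of -1.99 (SE 0.08, adjusted p = 1.24e-33, edgeR). Its KO amplitude was 0.54 (SE 0.13) against 0.93 (SE 0.11) in WT, and the KO rhythm did not pass the test (adjusted p = 0.157, edgeR). The test of a different rhythm gave it an unadjusted p of 2.74e-04 (edgeR) and did not call it over all features. Its KO mean was also lowest at 36 h, at 139 ± 40.4 CPM (SD, n = 4), so a loss of its rhythm is not shown. The feature with a rhythm in both genotypes had nearly the same wave in each. Its amplitude was 0.45 (SE 0.07) in WT and 0.45 (SE 0.07) in KO, with fitted peaks at 18.3 and 18.1 h and adjusted p of 3.28e-05 and 2.15e-04 (edgeR).

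**Figure D3:**
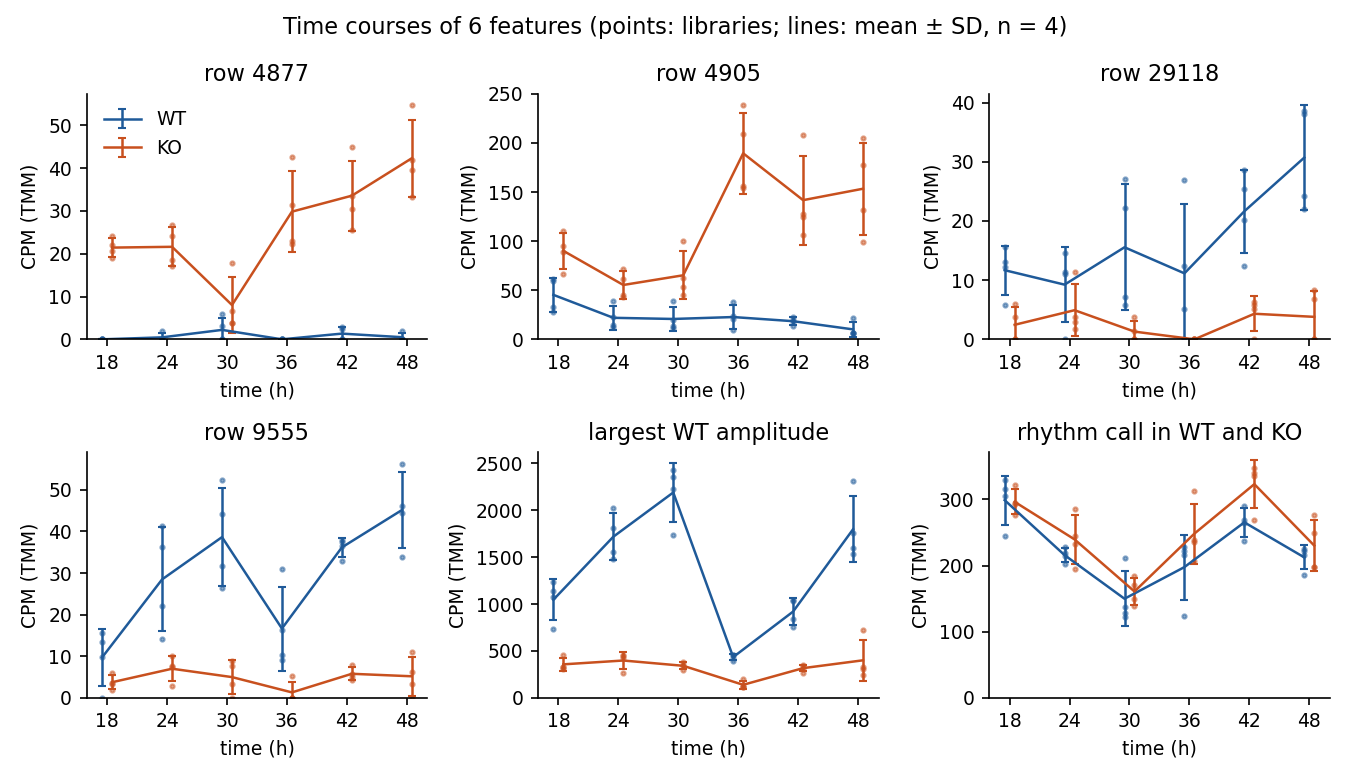
CPM (vertical axes) by time in hours for rows 4877, 4905, 29118 and 9555, the feature with the largest WT amplitude and the feature called rhythmic in both genotypes, with points for libraries and lines for the mean ± SD of 4 libraries, WT in blue and KO in orange. Row 4905 in KO went from 90.1 CPM at 18 h to 153.4 CPM at 48 h while WT went from 45.3 to 10.1 CPM. Between 30 and 36 h, where the library number changed, row 4905 went from 65.3 to 189.5 CPM in KO. In WT it went from 20.7 to 22.7 CPM there.

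Peak time and the direction of the change in KO went together. Of the 33 rhythmic features, 15 peaked between 24 and 30 h, and all 15 were lower in KO, by a median log2 change of -1.44. Both features that peaked between 30 and 36 h were lower too. Of the 10 that peaked between 36 and 42 h, 9 were higher in KO and 1 was not called, with a median log2 change of 0.72. The 6 that peaked between 42 and 48 h held 2 higher, 2 lower and 2 not called. The 24 to 30 h and 36 to 42 h sets differed in the sign of the change (two-sided Fisher exact p = 4.89e-06 over features, which are not independent), and this test was chosen after the values were seen.

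**Figure D4:**
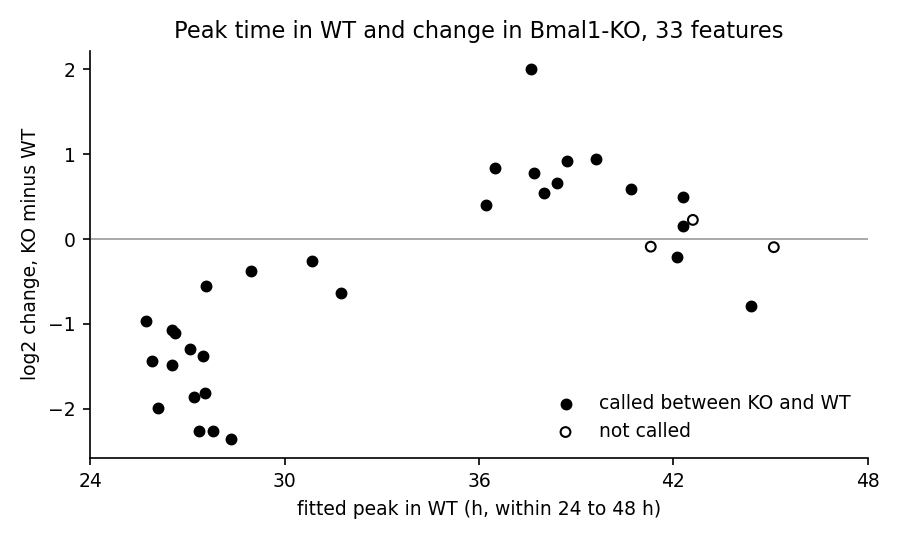
Log2 change of KO minus WT over all times (vertical axis) against the fitted WT peak in hours for the 33 features with a WT rhythm, filled where the change was called. The 15 features that peaked from 24 to 30 h lay below 0, and 9 of the 10 that peaked from 36 to 42 h lay above 0.

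Differences between times of any shape were more frequent than 24-h waves. An F test over the 6 times called 411 features in WT and 83 in KO, and 33 were shared where 3.96 would be for independent lists. The interaction of genotype and time called 32 features (edgeR quasi-likelihood, Benjamini-Hochberg). In each genotype the libraries from 18 to 30 h and those from 36 to 48 h had different library numbers, so these tests hold differences between numbers as well.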

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

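The tests of slopes, with and without the library number, were chosen after the time courses had been seen. The effect of genotype depended on time for 32 features by the interaction test. The linear slope over the time course differed between KO and WT for 186 features, with 1324 at an unadjusted p under 0.05. With the library number as a term 0 slopes differed, with 331 at an unadjusted p under 0.05, so a slope and a step between the early and late library numbers cannot be told apart, and the interaction crosses these numbers too. The interaction reached an adjusted p of 8.77e-05 for row 4905, whose mean CPM in KO was higher at each of 36, 42 and 48 h than at any of 18, 24 and 30 h, a step that falls where the library number changes, and 0.0218 for the feature with the largest WT amplitude (edgeR quasi-likelihood, Benjamini-Hochberg). Among the 33 features rhythmic in WT, the rhythm differed between genotypes for 3 after adjustment over these features alone. These features were selected for a strong WT wave in the same libraries, which favours such a difference, so the 3 are not evidence of one; over all features 0 passed in edgeR, with 317 at an unadjusted p under 0.05 where 430.8 were expected, and DESeq2 and limma called 0.

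Within groups of 4, 12 of 108 sets of values had 1 library far from the other 3, where about 1 in 20, or 5.4, would by chance. WT 36 h replicate 2 had 650414 counts where the other libraries of its group had 105849 to 195589, and KO 30 h replicate 4 had 691659 against 265267 to 309572. WT 18 h replicate 2, one of the 3 shallowest libraries, had 9463 features at equal depth against 9414 to 9417. Row 4877 was at 1.84 CPM in WT 24 h replicate 1 and 2.00 CPM in WT 48 h replicate 4, with 0 in the other libraries of each group, and row 9555 was at 5.23 CPM in KO 36 h replicate 4 with 0 in the others. Each of these 3 values is 1 count, which stands apart from 0 by construction, so the chance rate does not apply to them. Row 4905 was at 21.8 CPM in WT 48 h replicate 1 against 6.01 to 6.43. The feature with the largest WT amplitude was at 461.2 CPM in KO 18 h replicate 4 against 311.3 to 331.5, and at 267.9 CPM in KO 24 h replicate 3 against 426.4 to 454.5. The feature rhythmic in both genotypes was at 212.0 CPM in WT 30 h replicate 1 against 121.9 to 136.9, at 124.3 CPM in WT 36 h replicate 1 against 216.5 to 228.2, and at 269.4 CPM in KO 42 h replicate 4 against 335.0 to 346.9.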

How the results depend on the processing

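The alternatives of leaving out the 3 libraries under 100000 counts, thinning every library to 72398 counts, fitting the letter of the library name as a block and fitting the library number as a term were chosen after the data had been seen. The sums over all times were the most stable: under every other tool, filter, size factor and left-out library the features higher and lower in KO stayed within 1.5 times 1979 and 1963. Against a minimum change of 1.5-fold they numbered 159 and 200, and after thinning 812 and 770, where fewer counts were left. Rows 4877, 4905, 29118 and 9555 kept their direction and their call under each alternative run. Over the alternatives, 635 counts of calls stayed within 1.5 times the reported ones, 46 were lower and 29 higher. Many of the 635 could hardly move. Examples are counts at 1 time when a library of another time was left out, and rhythm differences of 0. Where a replicate number was left out, the 476 calls at 36 h became 227 to 252. The filter of at least 5 CPM in 4 libraries was planned as a stricter one but kept 12468 features, more than the 8617 of the main filter. The gene list tests, the clock genes and the targeted gene were not run because the rows carry no names.

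Calls at 18, 24, 30, 36, 42 and 48 h numbered 23, 66, 74, 38, 120 and 264 against a minimum change of 1.5-fold, and 119, 191, 66, 33, 90 and 233 after thinning. With only the 8 libraries of the time, 514 features were called at 24 h. Leaving out 1 replicate number or 1 library gave 1656 to 2004 features higher and 1553 to 2016 lower over all times, and at the 6 times in order 269 to 780, 424 to 962, 322 to 887, 227 to 535, 761 to 1499 and 863 to 1592. Single libraries that moved a count by over 1.5 times were WT 30 h replicate 4 (472 calls at 30 h without it), WT 36 h replicate 2 (243 at 36 h), KO 36 h replicate 3 (316 at 36 h), KO 36 h replicate 4 (293 at 36 h) and KO 48 h replicate 1 (998 at 48 h). The cause was not tested beyond the smaller number of samples.

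The rhythm counts moved in both directions, and the cause was not tested. WT calls were 95 with no filter, 63 with DESeq2, 16 with WT libraries alone, 411 for any difference between times, 65 with a linear term, 60 at a period of 22 h, 76 from 18 to 36 h only, 88 from 24 to 42 h only, 79 without the 3 shallow libraries, 126 with the library number as a term and 9 after thinning. KO calls were 29 with no filter, 8 with limma voom, 21 with DESeq2, 18 with KO libraries alone, 83 for any difference between times, 21 with a linear term, 3 at a period of 26 h, 2 from 18 to 36 h only, 58 from 24 to 42 h only, 15 without the shallow libraries, 3 with the library number as a term and 0 after thinning. Calls of a different rhythm were 1 with no filter, 32 for the interaction of any shape and 3 over rhythmic features only, and 0 otherwise. Leave-outs gave 15 to 70 in WT, 0 to 2 in KO and 0 for the difference; WT 24 h replicate 2 gave the 70, and WT 48 h replicate 2, KO 18 h replicate 4, KO 24 h replicates 1 and 4 and KO 30 h replicate 1 each gave 2 in KO. The feature rhythmic in both genotypes lost its KO call from 18 to 36 h only, after thinning and without replicate number 4.

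The replicate numbers did not pair the libraries: same-numbered libraries of different groups deviated together with a median correlation of -4.28e-05 over 264 pairs, from -0.355 to 0.455, and 16 of 48 libraries correlated best with their own number. With a replicate block, 1963 features were higher and 1941 lower over all times, 685, 931, 803, 514, 1319 and 1404 were called at the 6 times, and 36, 1 and 0 had a rhythm in WT, in KO and a different one. With the letter of the library name as a block, 1971 features were higher and 1944 lower, and 733, 964, 824, 457, 1375 and 1425 were called at the 6 times. Within a phase each letter went with 1 replicate number, so the letter block and the replicate block are not separate checks.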

Other observations

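The tests of a linear drift, of slopes, of the library number as a term, and of the direction in KO of the rhythm calls, and of KO peaks in separate replicates were chosen after the results had been seen, and the relation of peak time to direction was noticed in these data before its tests were set. Slopes along the time course were called in more WT features than waves were. With a linear term beside the wave, 65 features had a rhythm and 696 had a slope in WT, 291 rising and 405 falling, and 116 had one in KO (edgeR quasi-likelihood, Benjamini-Hochberg). With the library number as a further term 8 features had a slope in WT and 0 in KO, with 607 and 472 at an unadjusted p under 0.05, so drift over time cannot be told apart from a step between library numbers, which in each genotype changed between 30 and 36 h. Between 18 and 48 h, 479 features differed in WT and 16 in KO. WT libraries 24 h apart, at the same phase of the cycle, differed in 55 features between 18 and 42 h and in 200 between 24 and 48 h. Those 12 h apart, at opposite phases, differed in 60 features between 18 and 30 h, 48 between 24 and 36 h, 50 between 30 and 42 h and 108 between 36 and 48 h. Of these pairs of times, 18 and 30 h and 36 and 48 h lie within a library number, and the others cross numbers. In KO the pair of 30 and 42 h had the most calls, 115. Across 3961 features the WT and KO profiles over time correlated at 0.104 to 0.342 at the same time, and at no more than 0.129 between different times.

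The difference in features at equal depth between KO and WT was -209 with the 100 most abundant features removed, where 59134 counts were drawn and all features gave -262. Without the 3 shallow libraries it was -267 at 72398 counts, and 0 of the 4 library numbers held both genotypes. Of the 33 WT rhythm calls, 57.6% were lower in KO against 22.6% of the other features tested (two-sided Fisher exact p = 1.64e-05 over features, which are not independent), and 33.3% were higher against 22.9% (p = 0.152, same test). Calls of either sign made up 90.9% against 45.6% (Fisher exact p = 1.06e-07), and among called features the lower share was 63.3% against 49.7% (Fisher exact p = 0.147), so a preference for lower expression was not shown. The 33 were selected by a small rhythm p in the same libraries, and features with more counts or less spread pass both tests more easily. No comparison at matched counts was made, so a link between rhythm and a change in KO is not shown either.

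The difference between genotypes over all times was far from what regrouping gave. Of 100 groupings of the libraries within times, 1, the real one, gave as many as 3942 calls. The highest of the others gave 0, which argues against a random split of these libraries. The labels do not say whether the 4 libraries of a group are separate cultures. Regrouping libraries therefore cannot exclude a chance difference between cultures. With every library thinned to the smallest total 1582 calls were left, and without the 3 shallow libraries 3982, which argues against depth. Library number stays open: 0 numbers held both genotypes, so it cannot be told apart from the loss of Bmal1, and clonal differences between the lines were not tested. At single times, with fits of 8 libraries, 1 of 35 groupings, the real one, gave as many calls at each of 18, 24, 30, 36, 42 and 48 h. The real counts were 657, 514, 602, 583, 1838 and 1305, and the highest others 0, 0, 1, 5, 0 and 4. A random split of the libraries is argued against there too, with the same limit on cultures. A share of 1 in 35 is the smallest possible at 1 time.

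When times were reassigned within genotypes, 6 of 100 assignments gave as many rhythm calls in WT as the real 33, and the highest other gave 101, so chance is not excluded for the number. These fits had no term for the library number, and the reassignment crossed library numbers. With the library number as a term 126 features were called in WT, a count that was not set against reassignments. The source of the 101 calls, about 3 times the real count, was not tested. For KO, 3 of 100 gave as many as the real 1, a share under 0.05, but 2 of the 3 were reassignments that also gave 1, the highest other, and for the difference all 100 gave at least the real 0, with a highest other of 1. A linear drift is argued against, since all 33 calls stayed with a linear term. The letter of the library name may contribute, because each letter held 1 phase in both genotypes: in held-out replicates KO followed the WT waves at 0.653 ± 0.226 (SD over 6 splits) of the WT size, neither near 1 nor clearly under 0.5, so it cannot be told apart from a rhythm that KO cells share.

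Features peaking in WT from 24 to 30 h and from 36 to 42 h changed in opposite directions in KO. A hypothesis that waves of opposite phase lose BMAL1 as their driver was not tested. No feature passed the test of a different rhythm between genotypes, so none was shown to lose its wave in KO. The cosine fit gives a KO peak for every feature, so a fitted KO peak does not show a wave in KO. Of the 33, 1 had a rhythm call in KO. Over features with an unadjusted rhythm p under 0.05, counted by the sign of the change whether or not it was called, 83.9% of those peaking in WT from 24 to 30 h had a negative change and 87.1% of those from 36 to 42 h a positive one (odds ratio 34.9, 95% interval 20.4 to 61.7), and with the KO peaks in place of the WT peaks the shares were 83.8% and 84.6% (odds ratio 27.9, 15.2 to 53.4) over features selected on their own KO wave. With the cosine fit's own means 25 of the 25 features with a rhythm call kept their sign. Among the features with an unadjusted p under 0.05 and no rhythm call, 82.9% and 87.0% had these signs (Fisher exact p = 7.67e-54). Features are not independent, and peak and direction came from the same libraries here. An unadjusted p under 0.05 was reached by 860 features in WT where 430.8 were expected by chance. Whether the relation holds beyond the 33 was therefore not tested in separate libraries. With peak and direction from different replicate numbers, the largest Fisher exact p of 6 splits was 0.0392. Only 2 features peaked from 36 to 42 h in that split, and 2 to 9 did over the splits. The splits share libraries, so they are not independent of each other. Within these limits the splits argue against shared libraries for the 33 features of smallest WT rhythm p in each split, which are not independent. Depth alone is argued against, since the odds ratio stayed above 1 after thinning, at 9.46 (5.12 to 18.0). It was lower than the 34.9 with all counts, so a part of depth in the strength of the relation is not excluded. Thinning also left fewer counts, and the intervals treat features as independent. The library letter stays open: the KO odds ratio of 27.9 met the outcome set in advance for a letter effect, an interval reaching that of WT, but each letter held 1 phase, so letter and phase cannot be told apart, and with KO peak and direction from different replicate numbers the relation had the same sense in 6 of 6 splits, with Fisher exact p from 2e-04 to 0.524.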
